A study of Mus musculus with 18 samples.

How the data were processed

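RNA and ribosome footprints were profiled from the left ventricles of 9 male mice aged 20 weeks, 4 wild type and 5 lacking mORF4/NBDY, the small protein encoded by Nbdy. Each heart gave 1 poly-A RNA library and 1 footprint library, so 18 libraries were used. Per the labels' protocols, RNA was extracted with TRIzol, RNA libraries were made with a TruSeq kit that does not mark strand, and footprint libraries with a NEXTflex small RNA kit. Reads from a gene and an overlapping or antisense partner therefore cannot be told apart in the RNA libraries. Per the submitters' processing notes, STAR 2.7.1a, HTSeq and DESeq2 were used on the GRCm38 (mm10) build, with no role or order given.

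The authors deposited 3 tables of the same 10597 genes. The rule by which these genes were chosen is not given in the sources used here. The RNA and footprint tables hold a normalized read signal per library, which per the file headers and the values the authors made by dividing gene counts by 1 size factor per library. The efficiency table deposited by the authors holds the ratio of footprint to RNA signal of the same heart, and the deposited values differed from that quotient by at most 0.0497%. Each deposited table also holds a log2 fold change, per the file headers. The deposited p-value columns come with adjusted values for 10593 genes in RNA, 10299 in footprints and 10579 in efficiency, which match a Benjamini-Hochberg adjustment over those genes within 8.32e-05. The deposited efficiency fold change is wild type over knockout, since 95.3% of genes have the opposite sign to the difference computed here, while the deposited RNA and footprint fold changes are knockout over wild type. The deposited footprint fold changes are smaller than those fitted here, with a slope of 0.291 on them against 0.897 for RNA. How they were made is not given in the sources used here. For Nbdy, DESeq2 on whole footprint reads gave a log2 fold change of -3.66, against -1.15 deposited. The DESeq2 adjusted p and the deposited one were both 5.31e-13, so the smaller deposited value does not reflect weaker evidence. All fold changes printed here are knockout over wild type, and fitted here unless the authors' deposited table is named.

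Dividing by the smallest step in each library gave whole reads for 100% of values in every library, with a tolerance of 0.01 reads. Summed over the listed genes, RNA libraries held (M stands for 1e6) 11.2 to 12.4 M reads in wild type and 15.8 to 20.2 M in knockout. Footprint libraries held 6.67 to 36.7 M reads in wild type and 22.9 to 40.8 M in knockout. The knockout RNA libraries have too few low values for the step to be checked independently, so count tests were run only on the footprint reads, as an added alternative.

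The plan written before the data were examined named an edgeR quasi-likelihood test, on the assumption of raw counts. As the values are normalized, limma 3.58.1 was used in its place, in R 4.3.3, with a mean-variance trend on log2(value + 1) and a minimum mean of 10. Fold changes are on that scale, which understates the change of low genes. Benjamini-Hochberg adjusted p below 0.05 was the threshold. RNA and footprints were each fitted on genotype alone. Translational efficiency was tested as the genotype by assay interaction in 1 limma model over the 18 libraries. This main fit has no term for the heart, as the plan set it, so it treats the 2 libraries of a heart as independent. On simulated data with 200 genes changed, the RNA fit recovered 61.2%, 97.0% and 100% of changes of 0.5, 1 and 2 on the log2 scale. The footprint fit recovered 21.2%, 64.2% and 90.9% of the same sizes, and the efficiency fit 6.06%, 56.7% and 90.9%. Genes called though left unchanged numbered 8 in RNA, 4 in footprints and 12 in efficiency. The 2 libraries of a heart were simulated independently, so the effect of leaving out the heart is not shown.

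RNA and footprints of the same number come from the same heart, per the labels, so the numbers pair the libraries across assays. As a check, deviations from the genotype mean over 3233 well-measured genes were correlated between assays. The correlation was 0.277 to 0.662 within a heart, with a median of 0.442, against a median of -0.0992 between different hearts. Subtracting the genotype mean itself pushes correlations between different hearts of a genotype below 0, so part of this contrast is built in. In 7 of 9 hearts the RNA library correlated best with its own footprints. The fit with the heart as a replicate block was an alternative. Within genotype and assay no pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 6.04.

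Fixed before the data were examined were 32 gene lists, of which 27 had at least 3 measured members. They were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Genes named in the text follow a rule fixed at the same time. It takes the target, up to 10 largest rises and 10 largest falls among called genes with a mean of at least 50 and an established symbol, up to 4 called members per list with the smallest adjusted p, up to 2 members with the smallest p of a list with no called member, and listed genes within 1 Mb of the target. Genes chosen after their values were seen are marked so. Besides the genes marked in the text, Cnot3, Ndufa1, Ndufa2, Fabp3, Eif5b, Polr2c, Ifi27l2a and Myh7b overlap other listed genes. Symbols were found for 10560 of the 10597 identifiers. Coordinates are from RefSeq on GRCm38.p6. Alternatives covered filters, thresholds, pseudocounts, scaling, hearts left out, the replicate block, RNA reads thinned to the shallowest library, the authors' deposited adjusted p, and edgeR 4.0.16 and DESeq2 1.42.0 on the footprint reads.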

Results

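Left ventricles of 4 wild-type and 5 knockout mice were profiled for poly-A RNA, which measures the level of transcripts with a poly-A tail, and for ribosome footprints, the mRNA fragments protected by translating ribosomes. NBDY is a microprotein known to bind the mRNA decapping machinery in P-bodies. The comparisons ask how its loss alters transcript levels, ribosome occupancy, and occupancy relative to transcript level. Read totals over the listed genes averaged 11.8 ± 0.585 M (1e6 reads; SD, n = 4) in wild-type and 18.2 ± 1.68 M (SD, n = 5) in knockout RNA libraries, with no overlap between genotypes. Footprint totals averaged 21.9 ± 13.8 M (SD, n = 4) and 28.2 ± 7.26 M (SD, n = 5), and wild-type heart 2 was the shallowest at 6.67 M.

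**Figure D1:**
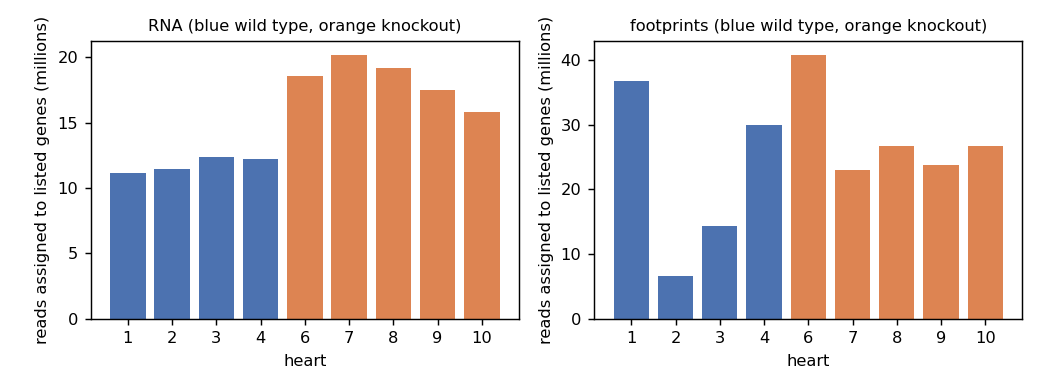
Reads assigned to the listed genes in each library, in M, for RNA (left) and footprints (right), with 1 bar per heart in blue for wild type and orange for knockout. Every knockout RNA library, from 15.8 M upward, lies above every wild-type RNA library, which reach 12.4 M.

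The targeted gene, Nbdy (X, 153723477 to 153741302, GRCm38), lost most of its footprints and part of its RNA. Footprints were 183 ± 116 normalized reads in wild type (SD, n = 4) and 14.3 ± 3.46 in knockout (SD, n = 5), or 7.78% of the wild-type mean. The log2 fold change was -3.45 ± 0.48 (SE; limma adjusted p = 0.0191). RNA was 111 ± 7.10 in wild type (SD, n = 4) and 73.5 ± 10.7 in knockout (SD, n = 5), a log2 fold change of -0.59 ± 0.13 (SE; limma adjusted p = 0.00246). All 5 knockout hearts lay below all 4 wild-type hearts in both assays. Efficiency fell by 2.85 on the log2 scale (limma adjusted p = 0.000275). The footprint call was lost without wild-type heart 1, 2 or 3, at adjusted p = 0.0978, 0.194 and 0.116, while the log2 fold change stayed between -3.64 and -3.07 in those fits. Of the listed genes within 1 Mb, Mageh1 RNA rose by 0.65 (limma adjusted p = 0.0129), and Ubqln2 and Kctd12b RNA differed by -0.03 and -0.15 without passing the test. None of these neighbours passed in footprints or efficiency.

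RNA levels differed between genotypes for many genes, in both directions. Of 10580 genes tested, 2570 were higher and 2660 lower in knockout, or 49.4% together. The larger direction turned at an absolute log2 fold change of at least 0.5 (1118 higher, 999 lower), at adjusted p below 0.1 (3020 and 3018), with TMM factors (2661 and 2604) and with quantile normalization (2628 and 2539). Most differences were small, with a median absolute log2 fold change of 0.45 among called genes, and 260 called genes differed by at least 1. The acyl-CoA thioesterases Acot4 and Acot5 rose by 1.75 ± 0.18 and 1.58 ± 0.24 (SE), and Atp5e, a subunit of ATP synthase, by 1.54 ± 0.11. Tmem160 rose by 1.52, Mrm1 by 1.46, Ramp1, part of the CGRP receptor, by 1.47, and Dedd2 by 1.67, and Abhd14b rose as well. Mid1, an E3 ubiquitin ligase, rose by 2.45 ± 0.46 and Ptprn2 by 4.99 ± 1.33. Over the alternatives, the authors' deposited values included, Mid1 ranged from 1.48 to 2.94 and Ptprn2 from 0.42 to 5.85. Ptprn2 was raised in knockout hearts 6, 7 and 8 alone and Mid1 in all knockout hearts but 9. Among the falls, Cox7a1, a muscle subunit of cytochrome c oxidase, changed by -1.61 ± 0.12, Cox7a2l, a respiratory supercomplex factor, by -1.51 ± 0.05, and Myl4, the atrial light chain of myosin, by -1.56 ± 0.14. Evi2b, Hrct1, Evi2, Meig1, Hspb11, Hcfc1r1 and Rtp3 had log2 fold changes between -1.81 and -1.44. All these genes passed limma at an adjusted p of at most 0.00891. Evi2b and Evi2 overlap Nf1, and Dedd2, Abhd14b, Myl4 and Hcfc1r1 overlap other listed genes, so their unstranded RNA values are uncertain. No batch is given in the labels, and because every knockout RNA library was deeper than every wild-type one, a batch of RNA libraries and the genotype cannot be told apart.

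By group, at the preset correlation, transcripts of histones, respiratory chain subunits and ribosomal proteins were shifted upward, and those of decapping factors downward. With an estimated correlation none of these 4 lists passed (adjusted p = 0.933 for each). Of 60 replication-dependent histone genes, 31 rose, 2 fell and 27 did not pass; 35 rose and 2 fell when adjusted over the list alone. The list passed camera with a median of 0.51 (adjusted p = 5.29e-05; adjusted p = 0.933 with an estimated correlation), and Hist1h1e and Hist1h4h rose by 1.59 and 1.03. Many histone genes are near-identical copies, so their single values are uncertain. The libraries hold poly-A RNA, so these values need not follow the level of histone transcripts without a poly-A tail. Of 77 nuclear-encoded oxidative phosphorylation genes, 48 rose, 17 fell and 12 did not pass; 49 and 18 when adjusted over the list alone (camera adjusted p = 0.00123; adjusted p = 0.933 with an estimated correlation). The 4 members with the smallest adjusted p went against the list, since Ndufs5, Uqcrb, Ndufs6 and Ndufa1 changed by -1.39, -1.29, -1.05 and -1.05. Of 83 cytosolic ribosomal protein genes, 44 rose and 18 fell; 44 and 19 when adjusted over the list alone (camera adjusted p = 0.00708; adjusted p = 0.933 with an estimated correlation), with Rps14 at 1.40, Rpl15 at 1.02, Rpl13 at 0.93 and Rpl8 at 0.71. Rpl13 and Rpl15 have 6 and 5 named pseudogene copies, so their values are uncertain. Of 30 P-body and decapping genes, 2 rose and 14 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0217; adjusted p = 0.933 with an estimated correlation). The deadenylase subunits Cnot3 and Cnot2 changed by -0.81 and -0.70, the decapping cofactor Pnrc2 by -0.66 and Lsm4 by -0.66.

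Other lists did not pass the set test in RNA, though members did. Of all genes tested in RNA 49.4% passed, so a count of called members near or below that share is no result about its list. In the fetal and hypertrophy programme 1 gene rose and 5 fell among 10, with Ankrd1 at -1.10, Rcan1 at -1.02 and Xirp2 at -0.64. Of 22 sarcomere genes 6 rose and 8 fell, with Myoz2 at -0.98, Des at 0.42 and Mybpc3 at 0.42. Of 45 translation factors 8 rose and 18 fell, with Eif5b at -0.77 and Eif3a at -0.66. Of 30 fatty acid oxidation genes 13 rose and 2 fell, with Cpt1b, the carnitine palmitoyltransferase of muscle, at 0.52 and Fabp3 at -1.05. Fabp3 has 1 named pseudogene copy with RNA values close to its own, so its value is uncertain. Among markers of other cell types, 4 of 15 endothelial genes rose and 6 fell, with Ly6c1 at -1.28, and 3 of 19 macrophage genes rose and 2 fell, with Cd68 at -1.05. Of 10 smooth muscle and pericyte markers 5 rose and 1 fell, with Pdgfrb at 0.45 and Notch3 at 0.42. Of 26 extracellular matrix and fibroblast genes 2 rose, Eln by 0.68 and Col1a2 by 0.49, and Col1a2 lost its call without heart 1, 3 or 4 (adjusted p = 0.0572, 0.0630 and 0.0576). Both measured lymphocyte markers fell, Ighm by 0.70 and Igkc by 1.08, and their footprints were at -0.93 and -1.29, past the test only when adjusted over the list alone. Of 6 skeletal muscle markers Myh1 and Myh4 fell by 1.07 and 1.02, uncertain values as myosin genes share sequence. Of 3 atrial markers 1 rose and 1 fell, 1 of 5 erythrocyte markers rose, Hbb-bs by 0.53, and 1 of 2 adipocyte markers fell, Cidea by 0.40. The lymphocyte and adipocyte lists had too few members for the set test. Counts adjusted over the list alone were equal for these lists, except 2 rises in place of 1 in the fetal programme and 1 in place of 2 in the extracellular matrix.

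Ribosome footprints differed for 2 of 9976 genes tested with limma, both lower in knockout. An unadjusted p below 0.05 was found for 505 genes, or 5.06%, about the share that this threshold gives with no change. The 2 genes past the test are named next. These were Nbdy and Nppb, the gene for brain natriuretic peptide (chromosome 4, 147985786 to 147987205, GRCm38). Nppb footprints were 13587 ± 2452 normalized reads in wild type (SD, n = 4) and 6945 ± 1437 in knockout (SD, n = 5), a log2 fold change of -0.97 ± 0.15 (SE; limma adjusted p = 0.0289). Nppb RNA was 1640 ± 334 (SD, n = 4) and 1878 ± 541 (SD, n = 5) and did not pass. Without any 1 of hearts 1, 2, 3, 6, 7, 8 and 9 the Nppb footprint call was lost, at adjusted p from 0.10 to 0.194, and with no filter on low values at 0.0587, and its log2 fold change stayed between -1.01 and -0.88. On whole footprint reads edgeR called 2 genes and DESeq2 6, and the authors' deposited table gives 6. The 4 further genes in the authors' deposited table were Cenpf and Myh8, higher, and Cpxm2 and Ighg2c, lower, named here after their values were seen.

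**Figure D2:**
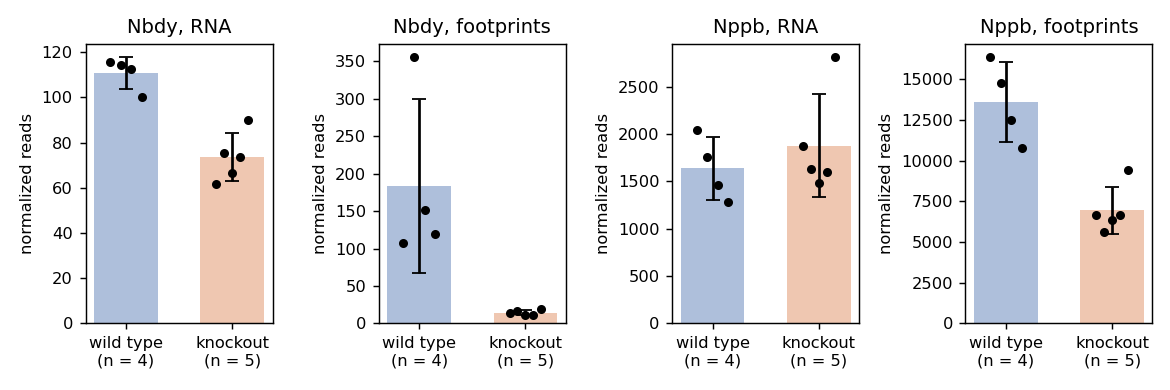
Normalized reads of Nbdy and Nppb in RNA and footprints, with a point per heart, bars for the mean and error bars for the SD (n = 4 wild type, n = 5 knockout). Nppb footprints average 13587 in wild type and 6945 in knockout, while Nppb RNA averages 1640 and 1878.

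Gene lists moved in footprints by small amounts. At the preset correlation 10 lists passed camera, while with an estimated correlation none did (smallest adjusted p = 0.631). Without heart 2, 8, 9 or 10 the number was 4, 5, 6 and 5. All 19 macrophage markers had lower mean footprints in knockout (median -0.27; camera adjusted p = 0.000822), with Cd74 at -0.52 and Ctss at -0.49, neither past the test. Their adjusted p was 0.631 with an estimated correlation and 0.316 without heart 2. The fetal and hypertrophy programme was lower (median -0.24; camera adjusted p = 0.00572), with 1 member lower over all genes and 3 when adjusted over the list alone; adjusted p = 0.631 with an estimated correlation. Immediate early genes were higher (median 0.31; camera adjusted p = 0.00886), with Egr1 at 1.54 and Jun at 0.46, and 1 member higher when adjusted over the list alone. Their adjusted p was 0.631 with an estimated correlation and 0.179 without heart 1. Oxidative phosphorylation was lower (median -0.09; camera adjusted p = 0.00886), with Ndufb2 at -0.35 and Ndufs8 at -0.31. The adjusted p was 0.631 with an estimated correlation, 0.316 without heart 2 and 0.0751 without heart 10. Extracellular matrix and fibroblast genes were lower (median -0.20; camera adjusted p = 0.0193), with Eln at -0.65 and Mfap4 at -0.63. Their adjusted p was 0.670 with an estimated correlation, without wild-type heart 2 their direction turned, at adjusted p = 0.895, and without heart 8, 9 or 10 it was 0.106, 0.175 and 0.0619. Fatty acid oxidation genes were higher (median 0.12; camera adjusted p = 0.0243; adjusted p = 0.650 with an estimated correlation). Nonsense-mediated decay factors, heat shock proteins, translation factors and sarcomere genes were higher with medians of 0.16, 0.17, 0.09 and 0.12 (camera adjusted p = 0.0338, 0.036, 0.036 and 0.0463; adjusted p = 0.631 with an estimated correlation for each). These 5 lists lost their calls without single hearts. For fatty acid oxidation these were hearts 2, 3, 8 and 9 (adjusted p from 0.120 to 0.273), and for nonsense-mediated decay hearts 1, 2, 8 and 10 (0.0540 to 0.316). For heat shock proteins they were hearts 1, 3, 6, 7 and 10 (0.0648 to 0.177), and for translation factors and sarcomere genes hearts 1, 2, 8, 9 and 10 (0.0540 to 0.605 and 0.0527 to 0.407). Sarcomere genes also lost the call with quantile normalization (adjusted p = 0.0788). Of the members of these 10 lists only Nppb passed the test over all genes.

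**Figure D3:**
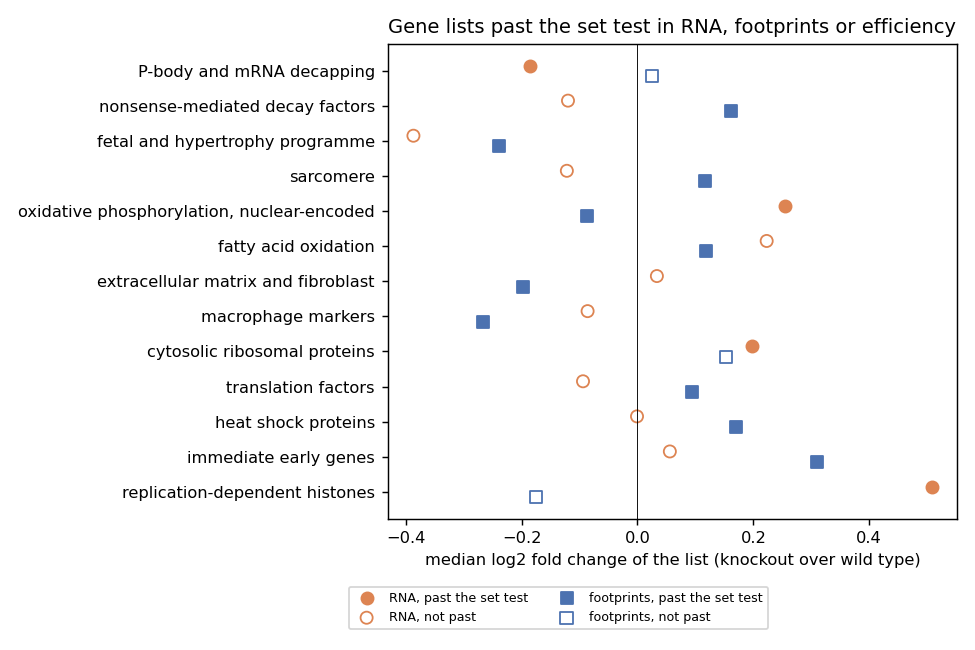
Median log2 fold change, knockout over wild type, of each list past the camera test in any comparison, in RNA (orange circles) and footprints (blue squares), filled where that list passed. Histones reach 0.51 in RNA and -0.18 in footprints, and oxidative phosphorylation 0.26 in RNA and -0.09 in footprints.

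Translational efficiency differed for 1434 of 9974 genes, with 781 higher and 653 lower in knockout (limma interaction). The larger direction turned in the paired fit with a replicate block (744 higher, 812 lower), with quantile normalization (621 and 693) and in the authors' deposited table (814 and 875). Nppb efficiency, the ratio of normalized footprint to normalized RNA signal, was 8.32 ± 0.229 in wild type (SD, n = 4) and 3.77 ± 0.442 in knockout (SD, n = 5). The log2 fold change was -1.15 ± 0.26 (SE; limma adjusted p = 0.0053). After Nbdy, the largest falls included Ckmt1, a mitochondrial creatine kinase, at -1.82, Atp5e at -1.77, Tmem160 at -1.58, Polr2c at -1.61, Pigyl at -2.08 and the linker histone Hist1h1d at -1.81. Tusc2, Ifi27l2a and Abhd14b, at -1.94, -1.69 and -1.62, passed narrowly. Tusc2 lost its call without heart 1, 2, 3, 6, 8, 9 or 10 (adjusted p from 0.0717 to 0.147) and in the paired fit with a replicate block (adjusted p = 0.0507). Ifi27l2a lost it without any heart but 6 (0.0637 to 0.101), and Abhd14b without heart 1, 3, 4, 7, 9 or 10 (0.0535 to 0.138). With quantile normalization Tusc2, Ifi27l2a and Abhd14b lost it too (adjusted p = 0.0661, 0.0704 and 0.0756), as did Ifi27l2a with no filter on low values (0.0504). The largest rises were Myh8 at 2.48, Cox7a2l at 2.24, the endothelial transcription factors Meox2 and Sox7 at 1.80 and 1.79, Myct1 at 1.90, Hrct1 at 1.87, Myl4 at 1.80, Hcfc1r1 at 1.75, Zfp384 at 1.73 and Myh7b at 1.71. Myl4 lost its call without heart 3 or 4, at adjusted p = 0.0666 and 0.0692. Myosin heavy chain genes share sequence, so Myh8 and Myh7b are uncertain. Of the 1434 genes, 1392 also passed in RNA, and 1391 of these in the opposite direction. Independent lists would share 715, but the RNA values enter both tests, so the overlap is not independent evidence. Of the 1434 genes, 2 also passed in footprints. A batch of RNA libraries, which cannot be told apart from genotype here, would by itself give efficiency calls opposite to RNA. Such calls are therefore not, on their own, evidence of changed translation.

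Oxidative phosphorylation and histone genes passed the set test in efficiency at the preset correlation, both lower in knockout. With an estimated correlation neither passed, at adjusted p = 0.694 for oxidative phosphorylation and adjusted p = 0.346 for histones. Both lists were shifted upward in RNA, so a batch of RNA libraries could by itself lower their efficiency. Of 77 oxidative phosphorylation genes, 9 rose, 30 fell and 38 did not pass; 10 and 37 when adjusted over the list alone (median -0.30; camera adjusted p = 4.37e-06), with Ndufa2 at -1.39, Ndufs7 at -0.81 and, the other way, Cox7a1 at 1.63. Of 32 histone genes 6 fell and 26 did not pass, with 6 when adjusted over the list alone (median -0.80; camera adjusted p = 0.00332), and Hist1h4d, Hist1h1e and Hist1h4c were at -1.63, -1.43 and -1.25. Without heart 3 the number of lists was 4 in place of 2, and in the paired fit with a replicate block 8, at the preset correlation. The added lists were P-body and decapping, nonsense-mediated decay, translation factors, sarcomere and circadian clock genes, higher, and extracellular matrix genes, lower (adjusted p = 0.0443 for each, except 0.0492 for sarcomere genes). With an estimated correlation in the paired fit none of them passed, at adjusted p = 0.322 for P-body and decapping, adjusted p = 0.466 for nonsense-mediated decay, sarcomere and circadian clock genes, adjusted p = 0.622 for translation factors and adjusted p = 0.545 for extracellular matrix genes. Among their members, Cnot3 and Cnot2 rose by 0.97 and 0.89, and Eif5b and Eif3a by 0.82 and 0.74.

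Across genes, footprint changes had little relation to RNA changes. Over 9974 genes tested in both, Pearson's r was 0.0689, Spearman's rho 0.0401 and the slope of footprint on RNA log2 fold change 0.06, and 50.6% of genes had the same sign. Over the 4973 genes called in RNA, r was 0.0625 and 50.4% had the same sign. Genes are not independent replicates, and these values describe the same 9 hearts. The authors' deposited table puts 1609 genes in a category named buffered and 8984 in one named unchanged.

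**Figure D4:**
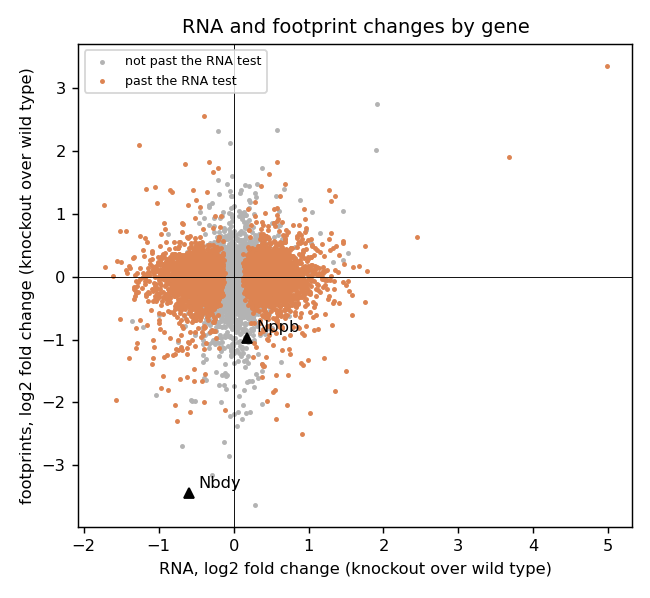
Log2 fold change in footprints against that in RNA, knockout over wild type, with a point per gene tested in both, orange where the gene passed the RNA test. Genes higher and lower in RNA are spread on both sides of 0 in footprints, with r = 0.0689 over 9974 genes, and Nbdy and Nppb are marked as triangles.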

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

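The tests of depth, slopes, histones and atrial markers were chosen after the results were seen, the depth test in place of an earlier one that higher precision alone would pass; those of gene copies and splits of the hearts were set before. Of 278 groups of values examined, 19 had a heart far from the others of its group, where chance gives about 1 in 20, or 13.9. In wild type, heart 2 stood apart in footprints of Eef1g (135 against 207 to 215), Hcfc1r1 (2143 against 1071 to 1214), Mfap4 (1874 against 783 to 866) and Myct1 (100.1 against 272 to 291), and it is the shallowest footprint library. Wild-type RNA stood apart for Col1a2 in heart 2 (2009), Meig1 in heart 3 (115), Myoz2 in heart 1 (44916) and Pigyl in heart 4 (18.9). In knockout RNA, heart 7 stood apart for Dedd2 (335), heart 6 for Ifi27l2a (209) and Eln (406) and heart 10 for Rpl13 (4047). In knockout footprints, heart 7 stood apart for Hspa1a (1955 against 34.6 to 211) and Eif3a (5156), heart 9 for Mageh1 (294), heart 10 for Myct1 (253) and Nppb (9398 against 5620 to 6678), and heart 6 for Rbm8a (837). The footprint depth of knockout heart 6, at 40.8 M reads, also lay apart from 22.9 to 26.7 M.

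RNA differed between genotypes for 5230 genes and footprints of the same hearts for 2. If the number of reads made the RNA calls, thinning every RNA library to the 11.2 M reads of the shallowest would remove them, yet 5022 to 5098 genes passed over 10 random draws, on knockout reads that could not be checked independently. Reads shared with named pseudogene copies do not account for most calls, since 4812 of the 5230 genes have no such copy. These were 49.3% of 9764 genes, which are most of the 10580 tested, so the share could hardly have come out low. Copies without such a name were not covered. Between genotypes the slope of footprint on RNA log2 differences was 0.038 ± 0.046 (jackknife SE) over the RNA-called genes, against 0.530 ± 0.098 between hearts of 1 genotype, a difference of -0.492 ± 0.112, so footprints did not follow these RNA differences as they follow those between hearts. A batch of RNA libraries and compensation at translation both give this and cannot be told apart, because genotype and RNA library depth coincide.

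Replication-dependent histone RNA was higher in the poly-A libraries of the knockout, with a median of 0.51 over 60 genes. The libraries need not follow the level of histone transcripts without a poly-A tail. The 32 histone genes measured in footprints had a median of -0.18 ± 0.33 (jackknife SE). If more cells were dividing, cell cycle genes would be higher too. Their RNA median was 0.075 ± 0.149 (jackknife SE) over 6 genes. That lay 1.20 jackknife SEs below 0.25, a bound set from the histone median after the results were seen. How far more dividing cells would raise these genes was not measured. The only member to pass, the proliferation marker Mki67, fell by 0.74 (limma adjusted p = 0.0319). That call was lost without heart 2, 3, 4, 6 or 9 (limma adjusted p from 0.0607 to 0.0975). The distance below the bound that would exclude more dividing cells was first set at 1 SE. It was widened to 2, to match the other tests, after the cell cycle median was seen. Too few genes are measured to decide, so more dividing cells and the RNA library difference above both stay open. Footprints of the 6 cell cycle genes had a median of 0.15, with 4 higher and 2 lower. None passed over all genes, and 1 was higher when adjusted over the list alone. Among them Cenpf was at 1.29 (limma adjusted p = 0.290), and is higher in the authors' deposited table.

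Nppb footprints were lower in knockout without lower RNA. Less atrial tissue in the knockout samples would lower footprints of other atrial genes alike, but the median footprint change of Myl4, Myl7 and Sbk2 lay 1.35 ± 0.44 (jackknife SE) above that of Nppb, and Sbk2 RNA rose by 0.85 (limma adjusted p = 0.0135). The markers did not move alike in RNA, where Myl4 fell by 1.56 and Myl7 was 1.53 higher without passing (limma adjusted p = 0.207). The fall of Myl4 RNA goes with less atrial tissue, as do Nppa footprints, which were lower by 1.23 without passing (limma adjusted p = 0.851). Apart from chance, below, no other cause was tested, and the Nppb footprint call is lost without any 1 of 7 hearts at log2 fold changes of -1.01 to -0.88, while Nppb efficiency, 8.32 ± 0.229 (SD, n = 4) in wild type and 3.77 ± 0.442 (SD, n = 5) in knockout, passed in every alternative (limma adjusted p at most 0.0195).

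Among 100 of the ways to split the 9 hearts into 4 and 5, the real one included, 1 gave as many RNA calls as the 5230 observed, and 1 as many efficiency calls as the 1434 observed, namely the real split in both cases. The highest of the others were 2377 and 110 genes, so chance is unlikely for these counts. With 100 splits no share below 1 in 100 can be shown, so chance is not excluded, nor is a batch that follows genotype. The 4 other splits with the most RNA calls, 1553 to 2377, each put 4 knockout hearts together. For footprints 7 of 100 splits gave at least the 2 genes observed and the highest other gave 15, with hearts 4, 8, 9 and 10 on 1 side, so chance is not excluded for that count, and that split points to a structure of the samples that was not tested.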

How the results depend on the processing

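The tests with other pseudocounts, scaling, the higher minimum mean for genes, lists without single hearts, the authors' deposited adjusted p and the tests on recovered footprint reads were added after the data were seen. The RNA count was 5230 and stayed within 1.5 times of it except at an absolute log2 fold change of at least 0.5 (2117), and the efficiency count of 1434 except at adjusted p below 0.01 (649). The footprint count of 2 was 1 with no filter, 0 at adjusted p below 0.01, 6 in the authors' deposited table and 6 with DESeq2 on the recovered reads, and 0 to 3 with hearts left out. The edgeR test on those reads gave 2 with either normalization. For Nbdy footprints the log2 fold change was -3.64 to -3.07 with hearts left out, and at adjusted p below 0.01 its value of -3.45 did not pass. It was -3.66 with DESeq2 on the recovered reads and -1.15 in the authors' deposited table, with the same adjusted p (5.31e-13 in both). The replicate block gave 1556 efficiency calls, 1200 of them shared with the unpaired fit, and 8 lists; of the efficiency calls printed for single genes it ended that of Tusc2 only. The lists past the test fell from 4 to 0 in RNA, from 10 to 2 in footprints and from 2 to 1 in efficiency at a correlation of 0.05, and to 0 in each with an estimated correlation. With hearts left out, 4 to 5 RNA lists, 4 to 12 footprint lists and 2 to 4 efficiency lists passed. Extracellular matrix genes turned direction in footprints without heart 2 (adjusted p = 0.895, from 9.06e-07 to 0.895 over the hearts left out). Ubqln2 RNA, not past the test, turned sign without heart 6 (2.08e-05, from -0.040 over the hearts left out) and with quantile normalization (0.0052), and Kctd12b efficiency, also not past, without hearts 3, 4 and 8 (0.041, 0.087 and 0.051, from -0.30 over the hearts left out) and with quantile normalization (0.069). The causes were not tested. With hearts left out, the correlation of footprint with RNA changes was 0.0439 to 0.0995 and the slope 0.0396 to 0.0955. In the other alternatives they were 0.0410 to 0.0880 and 0.0201 to 0.0770. Their jackknife SEs of 0.058 come from the same fits with hearts left out, so these fits can hardly exceed them. The SEs are also nearly as large as the main values of 0.0689 and 0.0585. Count tests of RNA and efficiency were not run, as knockout RNA reads could not be checked, nor were the alternatives planned for tables without values per heart (z test, ranked statistics, recomputed adjustment). Of simulated footprint changes of 0.5, 21.2% were recovered, with 200 genes changed in all. Changes in as many genes as passed in RNA were not simulated, so this share cannot tell whether low power explains the footprint count. In the measured footprints 5.06% of genes had an unadjusted limma p below 0.05, about the share that this threshold gives with no change.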

Other observations

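All genes here except Ptprn2, Mid1 and Hspa1a were chosen after their values were seen, and the p-values printed for them are from limma. In the cardiac stress programme, Acta1 and Nppa had lower means in knockout in both assays, while Myh7 did not in footprints. Acta1, skeletal alpha-actin, had a log2 fold change of -0.89 in RNA (limma adjusted p = 0.0239) and -1.25 in footprints (limma adjusted p = 0.293, not past). Nppa, the atrial natriuretic peptide gene and a neighbour of Nppb, had -0.79 in RNA (limma adjusted p = 0.0452) and -1.23 in footprints (limma adjusted p = 0.851, not past). Myh7, the slow myosin heavy chain, was at -0.12 in RNA (limma adjusted p = 0.653) and 0.73 in footprints (limma adjusted p = 0.854), neither past the test, and was uneven within both genotypes. Its footprints were 25983 in wild-type heart 4, 41100 and 36118 in knockout hearts 8 and 9, and 5550 to 10133 in the others, and its RNA was highest in the same 3 hearts. Myosin heavy chain genes share sequence, so the Myh7 values are uncertain. In wild type Myh7 efficiency averaged 0.0269, against 0.618 for Myh6, another myosin heavy chain gene. Within each genotype Myh6 RNA was also highest in these hearts. Edc4, the decapping scaffold, was 0.24 higher in RNA (limma adjusted p = 0.00929) and differed by 0.03 in footprints without passing.

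Some genes were nearly absent in some hearts and present in others of the same genotype, in both assays. Of 9974 genes examined, 7 varied within a genotype by at least 4 on the log2 scale in RNA and in footprints, with a correlation across the 9 hearts of at least 0.9 by selection. Ifi202b (chromosome 1, 173962569 to 173982844), an interferon-inducible gene, was at 45.6, 97.4, 50.6 and 71.2 normalized RNA reads in hearts 3, 4, 8 and 9 and listed at 0 in the other hearts, and its footprints were 54.5, 172, 59.9 and 151 in those hearts and at most 0.961 in the others. Hsd17b7 (chromosome 1, 169949535 to 169969242) was at 8.12 to 19.0 RNA reads in hearts 4, 8 and 9 and at 111 to 387 in the others. Fbxo44 (chromosome 4, 148152799 to 148160183) was at 12.8 and 12.6 RNA reads in knockout hearts 6 and 7 and at 73.4 to 246 in the others. Hearts 4, 8 and 9 are also those with the highest Myh7. The labels give 1 strain for all hearts, and a mixed genetic background was not tested and stays open, for these genes as for Ptprn2 below. Hspa1a and Hspa1b RNA, encoding inducible heat shock proteins of near-identical sequence, reached 26985 and 26762 in knockout heart 7. Angptl4 and Fos varied as well.

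The RNA rises of Ptprn2 and Mid1, the largest, rested on some of the knockout hearts. Ptprn2 RNA was 338, 354 and 310 in knockout hearts 6, 7 and 8, 5.80 and 5.40 in hearts 9 and 10, and at most 5.57 in wild type, and its footprints were 269, 237 and 59.1 in hearts 6, 7 and 8. Mid1 RNA was 563 to 772 in knockout hearts 6, 7, 8 and 10, 119 in heart 9 and 63.6 to 121 in wild type. Its footprints were at 45.9 ± 30.3 (SD, n = 4) in wild type and 56.4 ± 20.9 (SD, n = 5) in knockout, a log2 fold change of 0.64 that did not pass (limma adjusted p = 0.860).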
